A study of Mus musculus with 4 samples.

How the data were processed

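The data were RNA-sequencing libraries of sorted bone marrow pro-B cells from 4 mice, 2 per genotype. Per the labels' protocols, total RNA was isolated with an RNeasy Mini kit and libraries were made with the NEBNext low input RNA kit, for which no molecular identifiers are described, so counting intervals and floors cover counting error only. The submitters' processing notes name STAR 2.7.4a, SAMtools 1.10, deepTools 3.3.2, featureCounts, Subread 2.0.0 and DESeq2, with the builds GRCm38 and mm10. The gene annotation, strand setting and treatment of reads with several alignments are not given in the sources used here. Without a known strand setting, overlapping and antisense genes cannot be told apart, and 50 of the 140 genes chosen by the naming rule overlap another annotated gene.

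The authors deposited a table of raw counts for 24411 gene symbols, with whole numbers. They also deposited a second table of normalized signal, in which each value was the raw count times 1 factor per library (1.01, 1.22, 0.816 and 1.10 for controls 55 and 69 and knockouts 51 and 63). That table holds 13021 rows, of which 20 carry dates in place of gene symbols, and the other 13001 symbols match the count table. It was used in 1 alternative. The count table held 0 immunoglobulin or T cell receptor segment or constant region genes and no mitochondrially encoded genes, so 3 planned lists by symbol prefix were empty.

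Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total count of 15, which left 13507. Libraries were scaled by TMM, and genotypes were compared with the quasi-likelihood F test (glmQLFit, glmQLFTest) over all 4 libraries without covariates. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The mouse numbers are not shared between genotypes, and the labels give no batch. CPM are counts scaled to a common library total after TMM, given as mean ± SD over 2 libraries. Standard errors of log2 fold changes were computed as the fold change over the square root of the F statistic. With the common dispersion of 0.0630, the biological coefficient of variation was 0.251. A count of 3 in a library corresponded to 0.0743 to 0.113 CPM. Where a genotype held 1 to 3 counts of a gene, the ratio of the summed counts is given with an exact 95% interval. Replicates were compared by a chi-square of their counts, which averaged 89.3 per gene for the controls and 64.5 for the knockouts, so no library was a repeat of another.

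Before the data were examined, 29 gene lists, the rule for named genes, the tests and the alternatives were fixed. A list of cytosolic ribosomal proteins was taken by symbol, and Xist with Y-linked genes was used only for levels per library. This left 29 lists for testing with camera from limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 29 lists, each with at least 5 measured members. The same test was run with an estimated correlation, and fry was run beside it. Camera called 16 lists, none of which passed with an estimated correlation (0 lists, lowest adjusted p 0.65). Fry called 4, namely the lists of B-lineage transcription factors, pro-B surface genes, V(D)J recombination and erythroid genes. Fry asks whether a list's genes move, on balance, one way, and does not compare a list with other genes. List medians did not change when genes at 0 in a genotype were set at their bound of 3 counts.

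The named genes were Tnpo3, the 10 higher and 10 lower genes with the largest fold change that passed, had a mean log2 CPM of at least 3 and were separated in all 4 libraries, leaving out clone-named genes and receptor segments, up to 4 members per list with the lowest adjusted p, and regulators of B and T cell development and of the cell cycle fixed in advance. Some of the genes that the rule names are not reported here. Other genes in the text were chosen after their values were seen, or as sort markers. Coordinates are from the RefSeq annotation of GRCm38.p6, in which 23194 of the 24411 symbols were found. Alternatives were DESeq2 size factors in edgeR, total counts without scaling, no filter, a stricter filter (1 CPM in 2 libraries and a mean of 50 counts), DESeq2 1.42.0, limma-voom, limma on log2 of the authors' normalized values plus 1, a false discovery rate of 0.1, a fold threshold of 1.5, and each library left out in turn. After the data had been seen, the sex of each mouse was read from Xist and Y-linked genes, and sex, and for comparison the opposite pairing of the mice, was added to the edgeR model as a block. Leaving 1 library of a genotype assumes that the lone library varies like the others.

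The edgeR procedure was tested on simulated data with 200 changed genes among 13292 tested. For simulated knockout against control, it recovered 80.3% of genes changed 4-fold, 14.9% of those changed 2-fold and 1.49% of those changed 1.5-fold, with 8 unchanged genes among 72 calls. Far more genes changed in the data than in the simulation, which sets another threshold, so these rates do not carry over to the data. Camera called a simulated list of 20 raised genes and 0 of 40 random lists. Genes were simulated independently, so this check does not cover lists whose genes vary together. In the data, DNA replication genes had an estimated correlation of 0.97.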

Results

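Messenger RNA was measured by sequencing in pro-B cells, the early B cell precursors of the bone marrow, sorted from C57BL/6 mice as cells carrying B220, CD43 and the heat-stable antigen CD24. Both genotypes carried mb1Cre, a Cre recombinase expressed from the Cd79a locus. The 2 control mice (numbers 55 and 69) had intact Tnpo3 alleles, and the 2 knockout mice (numbers 51 and 63) had floxed Tnpo3 alleles. Tnpo3 encodes transportin 3, a nuclear import receptor that carries serine- and arginine-rich splicing factors among other cargo. Total counts were 32697489 and 26211372 in controls 55 and 69, and 40647384 and 30440627 in knockouts 51 and 63. Because each library came from its own mouse, the tests measure the spread between animals, with n = 2 per genotype. Log2 CPM values correlated across genes at 0.975 between the 2 controls and at 0.976 between the 2 knockouts, against 0.877 to 0.899 between genotypes. The first principal component held 79.7% of the variance and separated the genotypes.

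Tnpo3 itself, the targeted gene, was measured first. Its level was 159 and 148 CPM in controls 55 and 69, and 79.7 and 68.8 CPM in knockouts 51 and 63. The fitted log2 fold change was -1.05 ± 0.14 (SE), with an adjusted p of 0.0108 by edgeR's quasi-likelihood test. Without knockout 63 the log2 fold change was -0.94 and the adjusted p 0.0603. Whole-gene counts (GRCm38 chromosome 6, 29540827 to 29609858) do not separate transcript of exons outside the floxed part from transcript of cells with intact Tnpo3, and what share of the knockout libraries such cells made up was not measured. The annotated gene body overlaps that of Irf5. Of the genes that encode the sort markers, chosen for that reason and not by the rule for named genes, Cd24a fell (2095 ± 268 CPM in controls and 536 ± 66.9 in knockouts, SD, n = 2) and Spn, which encodes CD43, rose (210 ± 72.4 and 420 ± 33.9 CPM). In edgeR the adjusted p was 0.00725 for Cd24a and 0.0492 for Spn, the latter close to the threshold. Ptprc, whose products include B220, was at 561 ± 268 CPM in controls and 960 ± 69.1 CPM in knockouts, with an adjusted p of 0.168. Gene counts do not separate B220 from other products of Ptprc. Xist was at 1192 and 1712 CPM in control 55 and knockout 63, and at 0.376 and 0.668 CPM in control 69 and knockout 51, where the Y-linked gene Ddx3y was at 120 and 97.4 CPM, so each genotype held 1 female and 1 male.

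**Figure D1:**
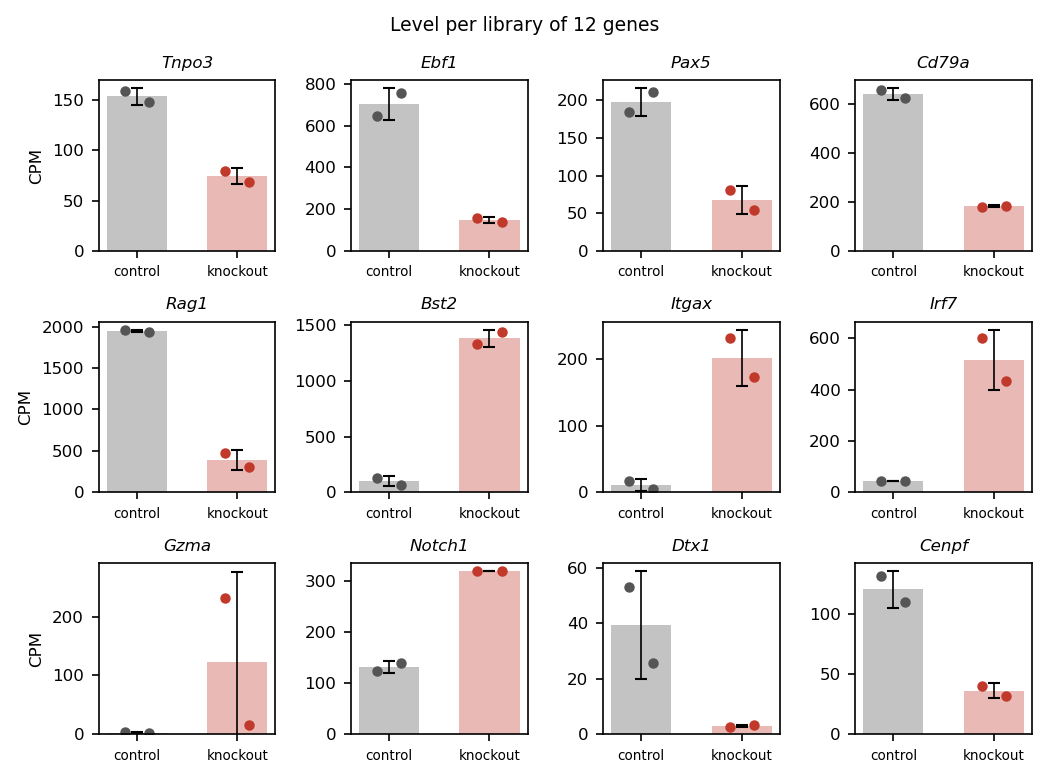
Levels in CPM (counts scaled by library size, linear axes from 0) of 12 genes. Points are single libraries, bars are the mean of 2 libraries per genotype and error bars are 1 SD; Gzma was at 231 CPM in knockout 51 and 14.7 CPM in knockout 63.

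The comparison of knockout with control asked which transcripts differ between the sorted cells of the 2 genotypes. It does not separate a change within cells from a change in which cells were sorted. Of 13507 genes tested, 1524 were higher and 1468 lower in the knockout at a false discovery rate of 0.05. With the sex of the mice as a block, an alternative chosen after seeing the data that leaves 1 residual degree of freedom, 2137 were higher and 2186 lower, against 985 and 821 with the opposite pairing of the mice. Among the changed genes with the largest fold changes, the higher ones included the cytotoxic granule proteases Gzmb and Gzma (log2 fold changes of 6.00 ± 1.47 and 5.87 ± 1.41, SE), the natural killer receptor gene Ncr1 (5.24 ± 1.13), the transcription factor gene Eomes (5.23 ± 1.19), the chemokine gene Xcl1 (5.15 ± 1.04), Klrc1, Klra7, Adgrg5, Apod and Cd4. Most of these were far higher in knockout 51 than in knockout 63. Ncr1, for example, was at 63.4 and 7.2 CPM. Without knockout 51 the log2 fold changes of Gzmb, Gzma and Ncr1 were 2.80, 2.82 and 2.95, and Eomes, Klrc1 and Klra7 had adjusted p-values of 0.0617, 0.0691 and 0.10. With limma-voom 7 of these 10 genes (Gzmb, Gzma, Ncr1, Eomes, Klrc1, Xcl1 and Klra7) did not pass, at adjusted p-values from 0.110 to 0.233. Gzmb also missed the threshold without control 55 (0.0501) and with limma on the authors' normalized values (0.0507), and Klra7 without control 69 (0.0504), with the stricter filter (0.0532) on the authors' values (0.0543) and with sex as a block (0.0535). The lower ones included the eosinophil granule genes Epx and Prg2, the mast cell and basophil protease gene Prss34, Ear1, Fcnb, the collagen gene Col5a3, Tmem132e, Cacna2d1, Cpm and Heyl. Tmem132e was at 56.4 ± 1.68 CPM in controls and 0.658 ± 0.0855 CPM in knockouts. Epx had 1 count over both knockout libraries, a ratio to control of 0.000407 with an exact 95% counting interval of 1.03e-05 to 0.00227. Prss34 also had 1 count, a ratio of 0.000848 (2.15e-05 to 0.00474). Col5a3 had an adjusted p of 0.0547 with limma-voom and Ear1 of 0.0599 with DESeq2. The log2 fold change of Ear1 ranged from -11.95 to -4.69 with a library left out. Reads of Klra7, Ear1 and the granzyme genes may be shared with close paralogs, so their values are uncertain. The number of changed genes was 1616 without knockout 51 and 1277 without knockout 63.

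**Figure D2:**
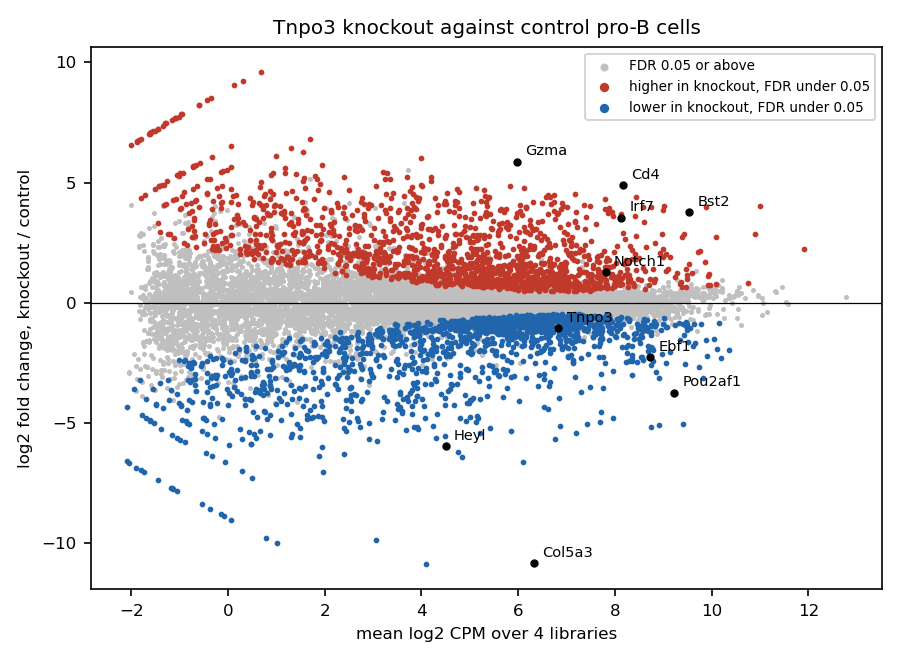
Log2 fold change (knockout over control) against mean log2 CPM for the 13507 tested genes. Red and blue points are the 1524 higher and 1468 lower genes, black points are named genes, and the diagonal streaks at low CPM are genes with few or no counts in one genotype, whose fitted fold changes depend on the prior count.

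Genes of the B-lineage program were lower in the knockout. Of 25 B-lineage transcription factor genes, 15 fell and 3 rose (16 and 3 adjusted over the list alone), with a median log2 fold change of -1.19. Pou2af1, a coactivator of octamer-binding factors, fell from 1114 ± 155 to 83.7 ± 0.554 CPM. Ebf1, a factor needed to specify the B lineage (chromosome 11, 44618100 to 45008096), fell from 702 ± 77.2 to 147 ± 13.5 CPM, with a log2 fold change of -2.26 ± 0.18. Pax5, Tcf3, Foxo1 and Myb fell with log2 fold changes of -1.55 ± 0.22, -1.64 ± 0.26, -1.43 ± 0.14 and -2.23 ± 0.18. Ikzf1 had a log2 fold change of -0.37 ± 0.22 and did not pass (adjusted p of 0.28), and was at -0.09 without control 55. The members that rose were Irf8, Tcf4 and Bcl11a, which are also expressed in dendritic cells. Of 26 pro-B signalling and surface genes, 17 fell and 2 rose (19 and 2 adjusted over the list alone). Vpreb3, Cd79a and Cd79b fell with log2 fold changes of -2.60, -1.81 and -2.54. Igll1, a surrogate light chain gene, was at 326 and 990 CPM in controls 55 and 69 and at 419 and 295 CPM in knockouts 51 and 63, and did not pass. Its log2 fold change was -0.88 with all libraries, -1.44 without control 55, where it passed (adjusted p of 0.00968), and 0.13 without control 69. Its log2 ratio was -0.15 between the females and -1.24 between the males, and with sex as a block it was at -0.69 (adjusted p of 0.0993). The camera test gave adjusted p-values of 0.000176 for the transcription factors and 3.25e-06 for the surface genes. With an estimated correlation the adjusted p was 0.65 for both lists.

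Some genes of antigen receptor recombination also fell. Of 20 measured genes of V(D)J recombination and end joining, 7 fell, 0 rose and 13 did not pass at the edgeR threshold (8 and 0 adjusted over the list alone), with a median of -0.43, a camera adjusted p of 0.00246 and 0.65 as the adjusted p with an estimated correlation. Rag1, a recombinase subunit, fell from 1945 ± 17.0 to 390 ± 120 CPM. Lig4, the ligase of end joining, fell from 128 ± 10.5 to 14.8 ± 0.739 CPM, and Xrcc6 and Polm fell with log2 fold changes of -1.83 and -3.46. Polm was at 265 and 100 CPM in controls 55 and 69, and its log2 fold change ranged from -3.99 to -2.56 with a library left out. Of 20 measured pre-B and later B cell genes, 11 fell and 2 rose (13 and 3 adjusted over the list alone), with a median of -2.03 and a camera adjusted p of 0.0573. With an estimated correlation the camera adjusted p was 0.896, and fry gave 0.466. Among the genes of this list, Cxcr5 fell from 45.1 ± 19.2 to 4.26 ± 1.68 CPM, and Cd55 and Ccr7 also fell. This list passed without control 69 (camera adjusted p of 0.00244), without knockout 63 (0.0218), without a filter (0.0245), with a stricter filter (0.0406) and with sex as a block (0.0209). Without control 55 its median was -1.34 and its camera adjusted p 0.238, and without knockout 51 the adjusted p was 0.0590. Of 18 genes of interleukin-7 receptor signalling, 4 fell and 3 rose (4 and 3 adjusted over the list alone), among them Pim1 (-1.19), Mcl1 (-1.03), Osm (-1.23) and Ccnd2 (0.95). Without knockout 51 Mcl1, Osm and Ccnd2 did not pass, and without knockout 63 Mcl1 and Osm did not. Osm was also lost without control 69. The list's median was 0.08, its mean -0.01 and its camera adjusted p 0.899. Il7r had a log2 fold change of -0.62 ± 0.23 and did not pass (adjusted p of 0.12), was at -0.37 without knockout 51 and passed with sex as a block (0.0175).

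Genes of other blood lineages moved with the genotype in both directions. Of 15 dendritic cell genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 fold change of 4.0. Flt3, a cytokine receptor gene, rose from 33.5 ± 8.96 to 458 ± 117 CPM, Bst2 from 101 ± 44.9 to 1379 ± 77.7, Lag3 from 8.69 ± 6.60 to 182 ± 26.2 and Itgax from 10.9 ± 9.03 to 202 ± 42.0. The mean log2 CPM of this list was 3.40 and 1.79 in controls 55 and 69, and 6.38 and 6.53 in knockouts 51 and 63, and its median log2 fold change was 5.41 without control 55 and 3.38 without control 69. Of 20 measured T cell genes, 11 rose and 0 fell (17 and 0 adjusted over the list alone), and 4 of the 20 reached 10 CPM in controls. Cd4 rose from 18.5 ± 16.0 to 553 ± 52.5 CPM and Cd8a from 3.82 ± 2.47 to 110 ± 13.5 CPM, both genes that subsets of dendritic cells also express. Thy1, Cd6 and Cd247 rose by 3.38, 3.73 and 2.84 on the log2 scale. Of 20 NK and innate lymphoid genes, 13 rose and 0 fell (16 and 0 adjusted over the list alone), including Il18r1, Il18rap, Klrd1 and Klrk1, the last with an adjusted p of 0.0633 by limma-voom. The mean log2 CPM of that list was 4.96 in knockout 51 and 3.11 in knockout 63, against 1.35 and 0.894 in controls 55 and 69. Without knockout 51 the median log2 fold change was 2.34 for the NK list, against 3.98 with all libraries, and 2.04 for the T cell list, against 3.52. The camera adjusted p-values were 4.45e-07 for the dendritic and T cell lists and 1.71e-05 for the NK list. With an estimated correlation the adjusted p was 0.65 for each of these 3 lists.

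Of 25 myeloid genes, 15 fell and 6 rose (15 and 6 adjusted over the list alone), with a median of -3.02 and a camera adjusted p of 0.0123. The adjusted p with an estimated correlation was 0.81. Without control 55 the camera adjusted p was 0.0589, and without knockout 51 the median was -4.31. Those that rose included the chemokine receptor gene Ccr2 (3.3 ± 0.29), Ly6c2 (3.85 ± 0.37), Csf2rb (2.19 ± 0.22) and Fcer1g (2.84 ± 0.29). Of 12 measured erythroid and megakaryocyte genes, 7 fell and 0 rose (10 and 0 adjusted over the list alone), with a camera adjusted p of 4.08e-06 and, as the adjusted p with an estimated correlation, 0.65. Slc4a1, the red cell anion exchanger gene, was at 29.2 ± 4.88 CPM in controls and 0.845 ± 0.775 CPM in knockouts, and Car1 and Klf1 also fell. The list's median was -2.79, or -1.88 without knockout 51 and -3.60 without knockout 63. The globin genes of the list are listed at 0 in every library. Of 18 measured stem and progenitor genes, 6 rose and 4 fell (7 and 4 adjusted over the list alone). Flt3 and Ly6a rose, and Cd93 and Sox4 fell, with a camera adjusted p of 0.479 for the list. Of 10 measured plasma cell genes, 1 rose and 2 fell (3 and 3 adjusted over the list alone), with Xbp1 higher and Irf4 and Slamf7 lower, and Jchain not past the threshold at 1.73 ± 0.53. Jchain was at 93.3 and 53.8 CPM in controls 55 and 69 and at 128 and 360 CPM in knockouts 51 and 63, and without knockout 63 its log2 fold change was 0.80 (adjusted p of 0.22). It passed with DESeq2 (adjusted p of 0.00302), without a filter (0.019), without control 55 (0.0323), without knockout 51 (0.0164) and with sex as a block (0.00319). Of 11 measured stromal and endothelial genes, 2 rose (Kdr and Cdh5) and 2 fell (Vcam1 and Col1a1), or 2 and 3 adjusted over the list alone. The stromal median was -0.34, or -1.10 without knockout 51 and -0.02 with the stricter filter. Col1a1 did not pass without control 55 or without either knockout. The knockouts held 3 counts of Col1a1, a ratio to control of 0.0485 with a counting interval of 0.00970 to 0.150. For the plasma and stromal lists camera gave adjusted p-values of 0.899 and 0.815.

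Genes of the Notch pathway, which directs precursors to the T lineage, moved both ways. Of 20 members, 4 rose and 6 fell (5 and 7 adjusted over the list alone), with a median of -0.16 and a camera adjusted p of 0.860. The receptor gene Notch1 (chromosome 2, 26457902 to 26503822) rose from 131 ± 11.8 to 318 ± 0.131 CPM, a log2 fold change of 1.28 ± 0.14. Notch3 rose from 3.55 ± 2.46 to 63.6 ± 31.5 CPM. Gata3, a T cell factor gene, rose from 0.242 ± 0.0829 to 3.08 ± 2.10 CPM, and its adjusted p was 0.0848 without knockout 51. Gata3 was at 4.56 and 1.59 CPM in knockouts 51 and 63, and NK cell genes were also higher in knockout 51. Dendritic and NK cell genes rose and B-lineage genes fell in the same libraries. The moves of Notch genes, Gata3 included, were thus not separated from a change in the sorted cells. Among genes known to respond to Notch, Heyl fell from 44.7 ± 24.0 to 0.712 ± 0.115 CPM and Dtx1 from 39.4 ± 19.5 to 2.88 ± 0.431 CPM. Hes1 had a log2 fold change of -0.72 ± 0.40, Tcf7 of 1.58 ± 0.58 and Myc of 0.66 ± 0.22, and these did not pass (adjusted p-values of 0.24, 0.11 and 0.090). Each depended on single libraries. The log2 fold change of Hes1 was -0.11 without control 69, that of Tcf7 0.65 without knockout 51 and that of Myc 0.42 without control 55, with adjusted p-values of 0.82, 0.44 and 0.12. Hes1 passed without control 55 (0.0275), Tcf7 without control 69 (0.0322), without knockout 63 (0.038), without a filter (0.0432) and with DESeq2 (0.0161), and Myc without control 69 (0.00608), without a filter (0.0446) and with DESeq2 (0.0481). With sex as a block Tcf7 and Myc passed (0.00491 and 0.0306), and Hes1 moved in opposite directions in the 2 sexes.

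Mitosis genes fell together. Of 22 members, 21 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -1.12, among them the kinetochore genes Cenpf (120 ± 15.2 to 35.9 ± 6.10 CPM), Cenpe and Ndc80 and the spindle gene Nusap1. The camera adjusted p was 8.83e-08, and the adjusted p with an estimated correlation 0.65. Dendritic and NK cell genes rose and B-lineage genes fell in the same libraries, so this fall was not separated from a change in the sorted cells. Of 28 DNA replication genes, 0 passed in edgeR in either direction and 0 adjusted over the list alone, with a median of -0.04 and a camera adjusted p of 0.827. With its estimated correlation of 0.97, far above the preset 0.01, the camera adjusted p was 0.951. The lowest adjusted p-values of this list were those of Rrm2 (0.12), Pola1 (0.15), Ccne2 (0.16) and Slbp (0.23). The mean log2 CPM of replication genes was 6.55 and 7.21 in controls 55 and 69. Without control 55 the list's median was -0.30 with a camera adjusted p of 0.00414, and without control 69 it was 0.30 with 0.0722. Rrm2 and Ccne2 passed without control 55 (0.0310 and 0.0467), and without control 69 their adjusted p-values were 0.29 and 0.47. With sex as a block both fell past the threshold (0.00981 and 0.0367), as 2 of the 28, and the list's median was -0.02 with a camera adjusted p of 0.779.

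Of 20 cholesterol synthesis genes, 17 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 1.67. Msmo1 rose from 16.6 ± 2.44 to 108 ± 62.0 CPM and Fdps from 33.7 ± 3.99 to 152 ± 59.7 CPM. The mean log2 CPM of the list was 5.80 in knockout 51 and 6.75 in knockout 63, and its median log2 fold change was 1.03 without knockout 63. Of 22 ribosome biogenesis genes, 11 rose, 0 fell and 11 did not pass (15 and 0 adjusted over the list alone), with Gnl3 (0.96), Wdr43 (0.75), Utp20 (0.69) and Dkc1 (0.63) at the lowest adjusted p-values. These 4 genes no longer passed without knockout 63, nor Wdr43, Utp20 and Dkc1 without knockout 51. Of 85 measured cytosolic ribosomal protein genes, 4 rose and 1 fell (0 and 0 adjusted over the list alone), with a median of 0.39, or 0.24 without knockout 51, and with sex as a block 24 rose and 1 fell. Of 17 measured glycolysis genes, 3 rose (Slc2a3, Pfkp and Ldha) and 1 fell (Slc16a3), or 4 and 1 adjusted over the list alone. Slc16a3 did not pass with the stricter filter (0.0521) or with any 1 of the 4 libraries left out, Ldha without control 55 or either knockout, and Pfkp without either knockout. The camera adjusted p-values were 4.45e-07, 2.46e-05, 6.20e-07 and 0.0317 for these 4 lists in turn. With an estimated correlation the adjusted p-values were 0.67, 0.65, 0.71 and 0.70. Dendritic cell genes rose and B-lineage genes fell in the same libraries, so these rises were not separated from a change in which cells were sorted. The glycolysis list had a camera adjusted p of 0.229 without control 55 and 0.154 without knockout 51.

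Stress and signalling lists differed in direction. Of 27 interferon response genes, 13 rose and 1 fell (15 and 2 adjusted over the list alone). Irf7, a regulator of type I interferon genes, rose from 44.2 ± 0.403 to 516 ± 117 CPM, and Mx1, Oasl2 and Mx2 rose by 3.07, 2.49 and 1.51 on the log2 scale. Dendritic cell genes rose in the same libraries (14 of 15, median of 4.0), and counts of sorted cells do not separate a response within cells from a change in which cells were sorted. Of 17 measured unfolded protein response genes, 7 rose and 1 fell (11 and 2 adjusted over the list alone). Manf, Pdia6 and Creld2 rose, while Syvn1, a ubiquitin ligase gene, fell from 478 ± 10.7 to 143 ± 30.2 CPM. Pdia6 and Creld2 did not pass without knockout 63 (0.0536 and 0.0646). Of 23 immediate-early and heat-shock genes, 10 fell and 0 rose (11 and 0 adjusted over the list alone), with Egr1 falling from 184 ± 8.30 to 18.5 ± 3.46 CPM and Dusp2, Jund and Ier2 also lower. The camera adjusted p-values were 9.76e-05, 0.00909 and 0.000189 for these 3 lists in turn, and the adjusted p-values with an estimated correlation were 0.65, 0.71 and 0.65. The immediate-early median was -1.12, or -0.43 without control 55. The unfolded protein list had a camera adjusted p of 0.110 without control 69. Of 18 measured integrated stress response genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone), with Slc7a5 and Slc3a2 higher and Atf3 and Ppp1r15a lower, and Slc3a2 did not pass without either knockout. Of 23 measured p53 target genes, 1 rose (Sesn2) and 5 fell, including Plk2, Trp53inp1 and Rrm2b, or 2 and 5 adjusted over the list alone. Cdkn1a, the p21 gene, had a log2 fold change of -0.05 ± 0.36 (-0.47 to 0.60 with a library left out), and Sesn2 did not pass without knockout 51 (0.0623). Of 19 measured apoptosis regulators, 1 rose (Bcl2, 0.89) and 3 fell (Bmf, -3.44, Bcl2l1, -2.08, and Mcl1), or 1 and 6 adjusted over the list alone, and Bcl2 did not pass without either knockout. For these last 3 lists camera gave adjusted p-values of 0.827, 0.899 and 0.124.

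Genes of splicing and nuclear import, the functions nearest to transportin 3, had small list medians at the level of total counts. The medians were -0.09 for serine- and arginine-rich proteins and their kinases, 0.03 for the core spliceosome and 0.04 for transportins and importins. Of 29 measured genes of serine- and arginine-rich proteins and their kinases, 2 fell and 0 rose (0 and 0 adjusted over the list alone), namely Tra2a (-0.55 ± 0.13) and Cpsf7 (-0.66 ± 0.17). With sex as a block 5 of the 29 fell and 1 rose. The kinase genes Clk1 and Clk4 had log2 fold changes of -0.73 and -0.66 and did not pass, although both did without control 69 (0.00736 and 0.00588), and Clk1 with DESeq2 (0.0402). Without control 55 they were at -0.36 and -0.30 (adjusted p-values of 0.21 and 0.24), and with sex as a block they passed (0.0240 and 0.0374). Of 34 core spliceosome genes, 1 rose (Snrpd3, 0.47 ± 0.12) and 0 fell (0 and 0 adjusted over the list alone), and Snrpd2, Dhx8 and Prpf3 did not pass, of which Snrpd2 did with sex as a block (0.0300). Tra2a, Cpsf7 and Snrpd3 passed neither without knockout 51, nor without knockout 63, nor without control 55. Snrpd3 was also lost without control 69, without scaling factors and with limma-voom, and Cpsf7 with DESeq2 size factors and with the stricter filter. Of 22 transportin and importin genes, 0 passed in edgeR in either direction, and 0 adjusted over the list alone, with Ipo4, Ipo9, Xpot and Ipo8 between 0.54 and -0.42, of which Ipo4 passed without control 69 (0.0335) and with DESeq2 (0.0435). With sex as a block 3 of the 22 rose and 2 fell, among them Ipo4, Ipo9 and Ipo8 (0.0349, 0.0447 and 0.0478). The camera adjusted p-values of these 3 lists were 0.449, 0.899 and 0.815. Fry's test for genes moving in either direction gave adjusted p-values of 0.0348, 0.145 and 0.0184 in turn. Small moves in both directions are therefore not excluded. This test does not compare a list with other genes, and 22.2% of all tested genes changed. Most of the other lists also passed it, so these values are not particular to splicing and import genes. Gene counts do not measure how transcripts were spliced or where proteins were.

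**Figure D3:**
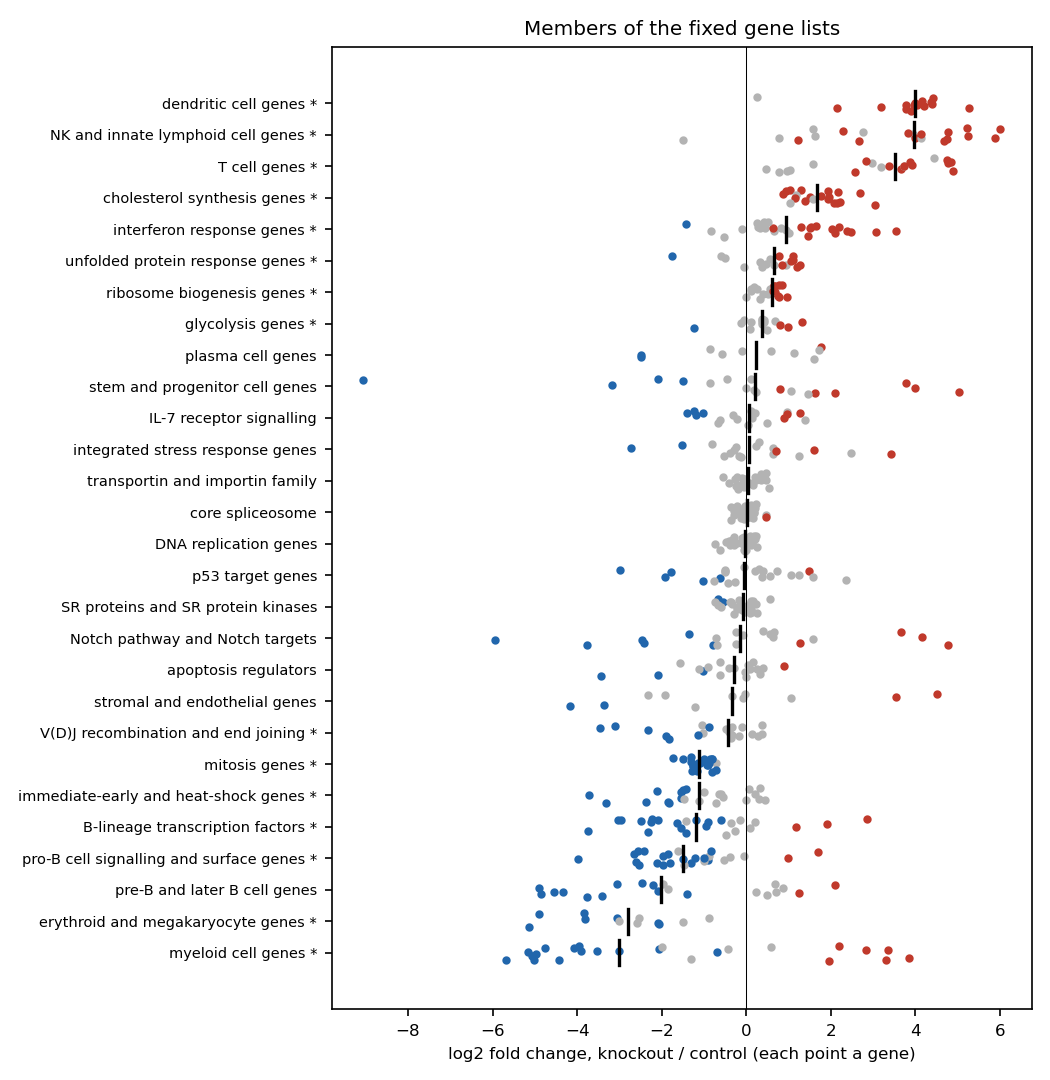
Log2 fold change (knockout over control) of each measured member of 28 gene lists. Red and blue points passed a false discovery rate of 0.05 in edgeR, grey points did not, black ticks are list medians, and an asterisk marks lists with a camera adjusted p under 0.05; dendritic cell genes had a median of 4.0 and myeloid genes of -3.02.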

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

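The split of changed genes into 1524 higher and 1468 lower stayed within 1.5 times under both other scalings, both filters, DESeq2 (2062 and 1894), limma-voom and limma on the authors' normalized values. The share of higher genes among changed genes ranged from 48.8% to 54.0% over these settings. With the sex of the mice as a block, chosen after seeing the data, there were 4323 changed genes, and with the opposite pairing 985 higher, 821 lower and 1806. Common dispersions were 0.0387 and 0.0829, against 0.0630 without a block. The counts of some lists also rose with sex as a block. Notch genes had 7 higher and 7 lower, plasma cell genes 4 and 3, glycolysis genes 6 and 1, and apoptosis regulators 1 and 6. Without a block these counts were 4 and 6, 1 and 2, 3 and 1, and 1 and 3. At a false discovery rate of 0.1 there were 2232 lower genes. Against a fold change of 1.5 there were 812 higher, 645 lower and 1457 changed genes. With a library left out, there were 747 to 1649 higher, 530 to 1580 lower and 1277 to 3229 changed genes. The lowest counts came without knockout 63, where 1178 of the 1277 were among the 2992 of the full comparison. Fits with as many libraries gave 2773 changed genes without control 55 and 3229 without control 69, so the number of libraries alone did not lower the counts, and why they fell without a knockout was not tested. Genes with few counts in a genotype, such as Epx with 1, are those whose ratios depth limits.

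The Tnpo3 log2 fold change ranged from -1.16 to -0.94 with a library left out, and stayed past the threshold in every setting reported for it but the one without knockout 63. Its results against a fold change of 1.5 and with the opposite pairing of the mice were not reported. The number of lists called was 15 to 17 in the other settings run for lists, which leave out the authors' values and the 2 other thresholds, 0 with an estimated correlation and 4 with fry. With an estimated correlation the lists' own co-variation between 2 mice per genotype enters the test, and so do the 2 residual degrees of freedom. Co-variation alone does not account for the lost calls. The estimated correlation was 0.00812 for B-lineage transcription factors, under the preset 0.01, and -0.0477 for V(D)J genes, yet both had adjusted p-values of 0.65. With so few degrees of freedom, a list not called there is not shown to be unchanged.

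Leaving out 1 library turned the sign of 2 named genes and 8 list medians, none of which passed with all libraries. Those fits compare mice of mixed sex, since each genotype held 1 female and 1 male. Igll1 ranged from -1.44 to 0.13, turning only without control 69, and Cdkn1a from -0.47 to 0.60. The log2 ratio of Igll1 was -0.15 between the females and -1.24 between the males. The list medians ranged from -0.0750 to 0.0342 for serine- and arginine-rich proteins, -0.0500 to 0.0887 for the core spliceosome, -0.28 to 0.24 for interleukin-7 signalling, -0.28 to 0.22 for Notch, -0.0787 to 0.76 for stem cell genes, -0.10 to 0.63 for plasma cell genes, -0.22 to 0.0511 for p53 targets and -0.30 to 0.30 for DNA replication. With sex as a block Cdkn1a and the p53 median were at 0.0465. Cdkn1a was at 0.0672 with limma-voom and 0.0600 on the authors' values, and the p53 median at 0.0672 with limma-voom. With the stricter filter the plasma cell median was -0.0919 and that of the integrated stress response -0.0925. Leaving out immunoglobulin and T cell receptor genes was not run, since 0 are in the table. Of 118 named genes that passed, other than Tnpo3, 38 moved by over 1.5 times in fold change when 1 library was left out, the most by 6.21 on the log2 scale (Ear1).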

Other observations

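The lists of lysosome, chromatin remodelling and endosomal Toll-like receptor genes, and all tests of explanations in this part, were chosen after the values had been seen. Of 30 lysosome genes, 20 rose and 1 fell in the knockout by edgeR, with a median log2 fold change of 1.09. Psap, the prosaposin gene, rose from 1355 ± 325 to 6373 ± 520 CPM (SD, n = 2), Ctsb from 284 ± 92.2 to 1884 ± 366 CPM and Grn from 175 ± 89.0 to 1157 ± 118 CPM, while Neu1 fell by 1.23 on the log2 scale. Of 12 measured endosomal Toll-like receptor genes, 6 rose and 1 fell, with Tlr7 rising from 24.8 ± 12.4 to 265 ± 47.4 CPM and Tlr13 falling by 3.76 on the log2 scale. Dendritic cell genes moved the same way, and 14 of 15 rose with a median of 4.0. Of 20 genes of the BAF chromatin remodelling complex, 5 fell, 1 rose and 14 did not pass, with a median of -0.39. Of all tested genes, 22.2% changed. Bcl7a fell from 861 ± 23.5 to 97.1 ± 3.14 CPM and Smarca4, the catalytic subunit gene, from 1742 ± 359 to 458 ± 87.4 CPM. The camera adjusted p-values over the 5 lists chosen this way were 9.86e-08, 0.00239 and 0.00220 for these lists in turn. Since the lists were chosen after their values had been seen, such p-values describe them and do not test them. With an estimated correlation the adjusted p-values were 0.25, 0.25 and 0.19.

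B-lineage genes fell while dendritic cell genes rose, which could come from a larger share of dendritic cells, some of which carry B220, among the sorted knockout cells. In the knockouts the dendritic cell gene Siglech stood at 1262 and 2305 CPM and Bst2 at 1379 ± 77.7 CPM. Such dilution as the whole cause would lower B-restricted genes by 1 factor, provided that the other cells expressed none of them, which was not measured. Over 11 such genes the widened 95% intervals of Pou2af1 and Cd79a were apart by 0.31 on the log2 scale. This rests on Pou2af1, and among the other 10 genes the intervals overlapped (gap of -0.79). Other cells that express some of these genes would also give unequal falls, so the gap does not exclude dilution, which stays open. Fewer later-stage B cells would lower the pre-B list further than the pro-B list, and the medians differed by -0.54 (permutation p of 0.290 over genes), or by -0.12 without control 55 and -0.92 without control 69, so this cannot be told apart from an equal fall. A direct effect of Tnpo3 loss on the B cell program, a change of cell fate, and an unknown share of cells with intact Tnpo3 stay open as well and were not tested apart from these.

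Granulocyte genes were abundant in the control libraries and scarce in the knockouts, with S100a8 at 934 ± 234 and 27.6 ± 23.4 CPM, S100a9 at 1318 ± 198 and 40.3 ± 35.9 CPM and Ngp at 836 ± 138 and 23.4 ± 16.7 CPM. A candidate explanation is granulocytes, or RNA from them, in the control sorts, although a gate on B220 should remove such cells. All 11 granulocyte genes of the myeloid list fell, with log2 fold changes from -5.68 to -3.90, and varied together between mice of a genotype with an estimated correlation of 0.99, against -0.01 for the 11 B-restricted genes but 0.97 for DNA replication, 0.91 for cholesterol synthesis and 0.84 for mitosis genes, so a high correlation is not particular to cells of another type. The mean log2 CPM of the 11 granulocyte genes was 7.42 and 7.10 in controls 55 and 69, and 3.26 and 0.977 in knockouts 51 and 63. Their correlation thus reflects mostly the 2 knockouts, where these genes were scarce, and says little about the control sorts. The widened intervals of these genes overlapped (gap of -4.19), a weak test because each interval is wide. A coordinated program within the sorted cells would also vary together, and why the genotypes differ stays open.

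With all libraries, mitosis genes fell and replication genes did not pass, but the replication median depended on the controls. It was -0.30 without control 55 and 0.30 without control 69, against -1.15 and -1.01 for mitosis genes. With the sex of the mice as a block the replication median was -0.02 (camera adjusted p of 0.779). The mean log2 CPM of mitosis minus replication genes was 0.43 and -0.09 in controls 55 and 69 and -0.80 and -0.94 in knockouts 51 and 63, a separation of 0.71 against a largest range within a genotype of 0.52. This restates the pattern and does not exclude a smaller share of cycling cells in the knockout sort, since other cells in the sort may express replication genes. A shift between phases of the cell cycle stays open too and was not tested.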
